A study of Mus musculus with 2 samples.

How the data were processed

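The samples were 2 small RNA libraries from heart tissue of male mice aged 18 to 20 months of the strain B6CASTF1/J, a hybrid of C57BL/6J and CAST/EiJ mice. MicroRNAs (miRNAs) are small RNAs cut from hairpin precursors that repress messenger RNAs, and miRNA-seq counts their reads. Per the labels, the size range of the library was under 30, and the starting material was total RNA. The labels call the libraries biological replicates 1 and 2 and place them in 1 group. They give each library its own biosample but the same donor record, so the spread between these libraries may be technical. Depending on the test, p-values rest on counting error, on the spread between these 2 libraries, or on genes or clusters. None measures the spread between animals. Because there is 1 group, no comparison between conditions and no model of group means was possible.

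The authors deposited read counts per miRNA gene, 1 table per library, with whole numbers that had not been normalized. Per the labels the reads were aligned to the mouse build mm10 (GRCm38), and per the text deposited beside each table the gene annotation was GENCODE release M21. The aligner, the counter, their versions and any trimming of adapters are not given in the sources used here. Each table has 2202 miRNA genes and 3 count columns, for reads on either strand and for each strand alone, after 4 summary lines for reads given to no gene (unmapped, mapped to several places, outside miRNA genes, ambiguous). The deposited text names no strand, so the strand column with more reads over miRNA genes in both libraries was used as the sense column, by a rule written before the data were examined. A miRNA gene on the opposite strand overlaps 64 of the miRNA genes, and the column for either strand has an ambiguous line and holds few or no reads at several of them that are abundant in the sense column, such as Mir126a (37 and 38 reads). Reads mapped to several places were counted for no gene, which can lower miRNAs made from near-identical hairpins. Reads of CAST/EiJ alleles that differ from the reference sequence could also be lost, which the counts cannot show.

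All 2202 gene IDs matched the GENCODE annotation, from which names, coordinates, overlapping genes and hairpin sequences were taken. The summary lines stayed out of library sizes and tests. In replicate 1, unmapped reads made up 19.4% of all reads, reads mapped to several places 40.7% and reads outside miRNA genes 7.79%. In replicate 2 these shares were 34.3%, 32.5% and 6.27%. Counts were scaled to reads per 1000000 reads in miRNA genes (CPM). The floor, the level that a count of 0 allows, was set at 3 reads, or 0.988 CPM in replicate 1 and 0.568 CPM in replicate 2. Intervals for shares are 95% Wilson intervals, and those for ratios of counts are exact binomial (Clopper-Pearson) intervals. No molecular identifiers are recorded, so intervals and floors cover counting error only. Means are given with the SD over 2 libraries.

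A miRNA gene was called detected with at least 10 reads in both libraries. Differences between the libraries were tested by an exact two-sided binomial test per gene, given the library totals, for genes with at least 10 reads in both together, with Benjamini-Hochberg adjustment and a threshold of 0.05. This test compares 2 libraries beyond counting error and says nothing of conditions. The replicate spread was estimated as the common dispersion of edgeR (estimateDisp, TMM scaling, genes with at least 10 reads in both libraries), and its square root is the biological coefficient of variation. Its error is the SD over 100 bootstrap draws of the genes. The same dispersion was given to the exact test of edgeR as an alternative. Its value comes from the same 2 libraries, so that test finds genes that stand apart from the usual gene in this pair. A count of 0 was replaced by 0.5 reads in log2 ratios. DESeq2 was used for size factors only.

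18 gene lists were fixed before the data were examined: muscle, endothelial, smooth muscle, fibroblast, erythroid, leukocyte, epithelial, brain, and liver and pancreas miRNAs, the families of let-7, miR-15, miR-17~92, miR-23/27/24, miR-29, miR-30, miR-34 and miR-378, and the imprinted Dlk1-Dio3 locus. Of their members, Mir486b, of the erythroid list, was not matched to a gene by name and has no value here. Mir3107, annotated on the strand opposite Mir486, was not counted in that list. On that strand 176 and 477 reads lay at Mir486 in replicates 1 and 2. Whether Mir3107 is the unmatched gene was not checked. For each list the median log2 ratio of the tested members was placed among 10000 random lists of the same size matched on mean expression. Genes are not independent replicates, so the percentile describes these libraries and is no p-value. The named genes were the 15 with the highest mean CPM, the up to 4 most abundant members of each list, Mir206, Mir208a, Mir208b and Mir499, and the 5 with the highest ratio in each direction among genes with at least 100 reads in both libraries together. Any other gene named was chosen after its values were seen.

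Hairpins were compared by exact 22-base stretches in either orientation. A stretch shared only with an overlapping miRNA gene, such as 1 on the opposite strand, was not counted. The planned search of the genome was replaced by a search among the 2202 annotated hairpins, because the genome sequence was not used here, so copies outside annotated miRNA genes were missed. The median log2(CPM + 1) of genes that share a stretch with another hairpin was compared with that of the other genes by a two-sided permutation test (100000 resamples). Clusters were miRNA genes on 1 strand with gaps of at most 10 kb.

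The tests were tried on simulated data. For the binomial test of replicate 2 against replicate 1, Poisson counts were drawn at the real levels and depths, and 419 genes passed the read minimum. It found 71.1% of genes changed by a log2 ratio of 1 and 51.0% of those changed by 0.5, rising to 96.4% and 76.6% among genes with at least 100 reads. It called 1 of 224 unchanged genes. Poisson counts have no spread between libraries beyond counting error, so these rates do not hold for the real pair. On 321 genes simulated with coefficients of 20%, 40% and 60%, the dispersion estimate gave 19.6%, 36.9% and 61.0%. The list test was tried on the real ratios, shuffled among genes and shrunk to a fraction of their spread. A list of 4 genes came out at percentile 91.7 of random lists unmoved and at 99.995 when moved by a log2 ratio of 2. Of 50 unmoved lists, 3 fell outside the central 95%. Because the spread was shrunk, this does not show how well a shift is found at the real spread.

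Alternatives were other read minimums, TMM and DESeq2 scaling, the column for either strand, all reads as the denominator, removal of the most abundant gene, another pseudocount (0.1), 18-base stretches and each library alone. A search for outlying samples and a paired analysis between groups need more samples or groups than 2 libraries of 1 group give. The software was R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.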

Results

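The miRNAs of the heart of old male hybrid mice (strain B6CASTF1/J, 18 to 20 months) were profiled in 2 libraries of 1 group, labelled biological replicates 1 and 2. Replicate 1 held 3037063 reads in miRNA genes, which was 32.1% of its 9468820 reads. Replicate 2 held 5284446 of its 19574873 reads. With 1 group, the data answer which miRNAs the tissue holds and how closely the 2 libraries match. At least 10 reads in both libraries were found for 321 of 2202 miRNA genes. Coordinates are those of the mouse build GRCm38 (mm10).

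Among reads counted for a gene, Mir378a, Mir126a and members of the let-7 family had the highest levels. Reads mapped to several places, 1.27 and 1.20 times as many as the counted reads in replicates 1 and 2, are not in this ranking. Mir378a (ENSMUSG00000105200.1, chromosome 18, 61397835 to 61397900, minus strand, in an intron of Ppargc1b, which encodes a coactivator of mitochondrial genes) had 130358 ± 14002 CPM (SD, n = 2). Mir126a (ENSMUSG00000065540.1, chromosome 2, 26591357 to 26591429, plus strand, overlapping an exon of the endothelial gene Egfl7), the miRNA of blood vessel endothelium, had 97534 ± 17380 CPM (SD, n = 2). Of the let-7 genes, Mirlet7b, Mirlet7i, Mirlet7g and Mirlet7d had 68411 ± 7298, 63798 ± 2258, 52696 ± 4177 and 50237 ± 727 CPM (SD, n = 2 for each). Mir23a (51660 CPM, above Mirlet7d), Mir23b, Mir143 and Mir139 were the others of the 10 most abundant genes by mean level, which together took 64.1% ± 3.30 (SD, n = 2) of the miRNA reads. That share was 66.4% in replicate 1 (95% Wilson interval 66.4 to 66.5) and 61.8% in replicate 2 (61.7 to 61.8). The next 5 genes were Mir99a, Mir26b, Mir149, Mir22 and Mir29a, with mean levels from 36867 down to 16912 CPM.

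**Figure D1:**
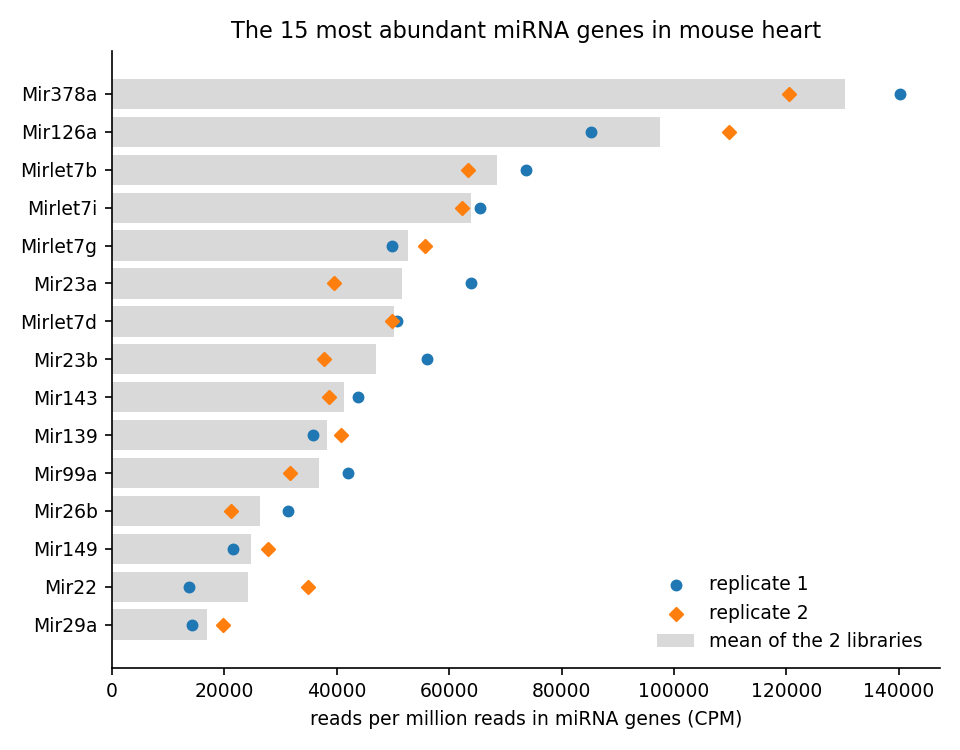
Level of the 15 most abundant miRNA genes in reads per 1000000 reads in miRNA genes (CPM) (linear axis from 0); bars give the mean of the 2 libraries, circles replicate 1 and diamonds replicate 2. Mir378a leads in both libraries with a mean of 130358 CPM, and Mir22 shows the widest gap relative to its mean, at 24219 ± 14982 CPM.

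By family and cell type, let-7 genes took 25.3% ± 0.499 (SD, n = 2) of the counted reads, from 13 of 14 members detected. Shares of different lists are not on 1 scale, because members that share a 22-base stretch with another hairpin can lose reads: 6 of 14 let-7 genes, 5 of 10 muscle genes, 3 of 4 miR-29 genes and 10 of 11 brain genes do. The miR-378 family took 13.1% ± 1.40, nearly all of it Mir378a, while Mir378d had 665 and 945 reads, Mir378c 101 and 164, and Mir378b 24 and 113 in replicates 1 and 2. The miR-23/27/24 list took 10.8% ± 2.79, led by Mir23a (51660 CPM), Mir23b (46906 CPM), Mir27b (6354 CPM) and Mir27a (2579 CPM). Endothelial miRNAs took 10.1% ± 1.97, most of it Mir126a, and Mir221 had 2910 ± 2038 CPM. Smooth muscle miRNAs took 4.32% ± 0.357, with Mir143 at 41182 ± 3596 CPM and Mir145a, from the same locus on chromosome 18, at 1985 ± 23.8 CPM. The miR-30 family took 3.53% ± 0.120, led by Mir30d (15038 CPM), Mir30a (11758 CPM) and Mir30e (6610 CPM). The miR-29 family, repressors of collagen messages, took 1.78% ± 0.424, led by Mir29a (16912 CPM) and Mir29c (846 CPM). Fibroblast miRNAs took 1.14% ± 1.07, an SD close to the mean because Mir21a had 1899 CPM in replicate 1 and 15190 CPM in replicate 2.

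Muscle miRNAs took 1.28% ± 0.281 of the reads (SD, n = 2), with 1.09% in replicate 1 (95% Wilson interval 1.07 to 1.10) and 1.48% in replicate 2 (1.47 to 1.49). Almost all of these reads came from Mir208a and Mir499, which lie in myosin heavy chain genes. Mir208a (ENSMUSG00000065432.1, chromosome 14, 54949060 to 54949142, minus strand, in an intron of Myh6) had 7169 ± 2807 CPM, and Mir499 (ENSMUSG00000076312.1, chromosome 2, 155622880 to 155622958, plus strand, in an intron of Myh7b) had 5523 ± 50.4 CPM. Mir206, known from skeletal muscle, had 5.59 ± 0.945 CPM. The miR-1 and miR-133 genes, chosen after their values were seen except for Mir1a-2, had few counted reads: 84 and 141 at Mir1a-2, 21 and 20 at Mir1a-1, 8 and 31 at Mir133a-1, 14 and 45 at Mir133a-2, and 28 and 51 at Mir133b in replicates 1 and 2. The first 4 hairpins each share a 22-base stretch with another hairpin. Mir133b shares none, and its longest stretch in common with Mir133a-1 and Mir133a-2 is 21 bases. Reads that mapped to several places were counted for no gene, so how many miR-1 and miR-133 reads were left out cannot be read from these counts.

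Mir208a and Mir208b mark the 2 main cardiac myosins, because they lie in introns of Myh6 (alpha myosin heavy chain) and Myh7 (beta myosin heavy chain, chromosome 14, with Mir208b at 54975700 to 54975776). Mir208a exceeded Mir208b 104-fold in replicate 1 (15744 against 152 reads, 95% interval 88.3 to 122) and 79.0-fold in replicate 2 (48375 against 612 reads, 73.0 to 85.7). The mean log2 ratio was 6.50 ± 0.28 (SD, n = 2), far above the spread between the libraries. An exact paired sign-flip test of 2 libraries cannot go below p = 0.5, so no test was made.

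Few reads were counted for markers of brain, liver and pancreas. Brain miRNAs took 0.0107% ± 0.00311 of the reads, led by Mir137 (55.4 CPM), and liver and pancreas miRNAs 0.0118% ± 0.000198, led by Mir192 (36.0 CPM) and Mir122 (21.3 CPM). Of the 11 brain members 10 share a 22-base stretch with another hairpin, so the brain share has the same limit as the reads of miR-1 and miR-133. Epithelial miRNAs took 0.0298% of the reads in replicate 1 (95% Wilson interval 0.0280 to 0.0318) and 0.387% in replicate 2 (0.382 to 0.393). Erythroid miRNAs took 0.820% in replicate 1 (0.810 to 0.830) and 0.254% in replicate 2 (0.250 to 0.259). In replicate 2 the largest part was Mir486 (0.132%), which is also made in muscle. There, Mir451a took 0.0948% and Mir144 0.0271%.

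Genes whose hairpin shares an exact 22-base stretch with another miRNA hairpin had any read less often than the others. Of 1032 such genes 10.2% had any read, against 53.8% of the other 1170. Only 1174 of the 2202 genes have a name starting with Mir, and 1 cluster alone holds 117 genes that share a stretch. Genes annotated as miRNA but not expressed may therefore be unevenly split between the groups, which was not tested. Among cluster neighbours chosen after their values were seen, Mir24-1 had 118 CPM beside Mir23b (46906 CPM). Likewise, Mir29b-1 had 29.4 ± 22.1 CPM (SD, n = 2) beside Mir29a (16912 CPM). The median log2(CPM + 1) differed by -0.22 (two-sided permutation test across genes, which are not independent, p = 1e-05, the smallest that 100000 resamples give). Among genes with at least 1 read the difference had the other sign, +1.48 (p = 0.00504, permutation test), and in each library alone both medians were 0, so the median difference rests on genes without reads.

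Levels of most detected genes were similar in the 2 libraries, while many genes differed by more than counting error. Across the 321 detected genes, which are not independent replicates, Pearson's r of log2 CPM was 0.969 and Spearman's rho 0.956. The median absolute log2 ratio was 0.38, and 261 of the genes (81.3%) lay within a log2 ratio of 1. Beyond that ratio, 33 were higher in replicate 2 and 27 higher in replicate 1. The biological coefficient of variation was 40.5% ± 3.17 (SD over bootstrap draws of genes). With replicate 2 sequenced 1.74 times as deeply in miRNA genes, 224 of 424 tested genes (52.8%) differed by more than counting error (exact binomial test, Benjamini-Hochberg), 131 higher in replicate 2 and 93 higher in replicate 1. With the common dispersion in the exact test of edgeR, 12 genes differed, 10 higher in replicate 2 and 2 higher in replicate 1. That dispersion was estimated from the same pair, so the 12 do not measure how closely the libraries match.

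Among genes with at least 100 reads in both libraries together, those higher in replicate 2 were led by Mir205, Mir135b, Mir31, Mir182 and Mir200c. Mir205 and Mir200c belong to the epithelial list, which as a whole lay inside the central 95% of random lists (median 0.43, percentile 90.4). Mir205 (ENSMUSG00000065533.1, chromosome 1, 193507463 to 193507530, minus strand, overlapping an exon of the noncoding gene 4631405K08Rik) had 7 reads in replicate 1 and 10372 in replicate 2, a log2 ratio of 9.73 (95% interval 8.69 to 11.05; adjusted p = 5.68e-12, exact test of edgeR). Mir31 (chromosome 4, 88910557 to 88910662) had 228 reads in replicate 1 and 15421 in replicate 2, a log2 ratio of 5.28 (adjusted p = 3.67e-05, exact test of edgeR). Mir200c (chromosome 6, 124718322 to 124718390, in an intron of Gm15884) had a log2 ratio of 4.32 and Mir182 (chromosome 6, 30165918 to 30165992) of 5.25, with adjusted p values of 0.000834 and 0.000154 in that test. Mir135b had 2 and 144 reads, a log2 ratio of 5.37 (95% interval 3.49 to 8.43). Mir21a, a miRNA raised in many injured tissues, had 5768 reads in replicate 1 and 80270 in replicate 2 (adjusted p = 0.0338, exact test of edgeR). The other 4 of the 10 genes were Mir34c (3.26) and, chosen after their values were seen, Mir183 (3.82), Mir26a-1 (3.27, from a hairpin with a near-identical copy) and Mir96, which had 0 and 49 reads and was at least 9.39-fold higher.

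The genes higher in replicate 1 included red blood cell miRNAs. Mir301 (chromosome 11, 87113004 to 87113089, in an intron of Ska2) had the lowest log2 ratio, -4.35 (422 against 36 reads; adjusted p = 0.000958, exact test of edgeR). Mir144 and Mir451a, neighbours on chromosome 11 (78073005 to 78073070 and 78073170 to 78073241) that are abundant in red blood cells, had log2 ratios of -3.06 and -2.37. Mir144 passed the exact test of edgeR with the common dispersion (adjusted p = 0.0298), and Mir451a did not (adjusted p = 0.226). Mir370 (-1.57) and Mir101a (-1.56) differed beyond counting error, with adjusted p values of 0.859 and 0.787 in the exact test of edgeR.

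**Figure D2:**
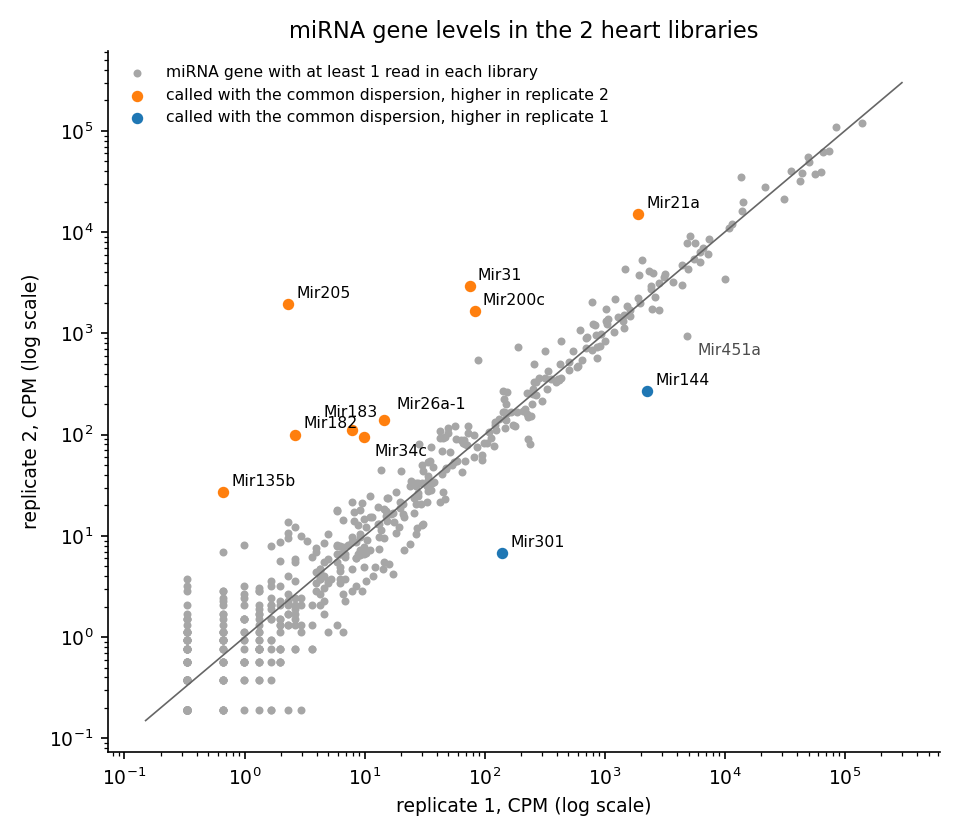
Level of each miRNA gene with at least 1 read in each library, replicate 1 against replicate 2, in CPM on log axes; the line marks equal levels and coloured points are genes called with the common dispersion. Mir205, Mir31 and Mir200c lie far above the line (log2 ratios 9.73, 5.28 and 4.32), Mir144 and Mir301 below it (-3.06 and -4.35), Mir451a is named without a call, and Mir96, with 0 reads in replicate 1, is not drawn.

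As groups, 4 of the 18 lists had a median log2 ratio outside the central 95% of random lists matched on expression. Some lists fall outside without a shift, as 3 of 50 unmoved lists did when the list test was tried. The erythroid list had a median log2 ratio of -2.37 (percentile 0.045). Beyond counting error, Mir144 and Mir451a of its 3 tested members were higher in replicate 1 and Mir486 (log2 ratio 0.35) higher in replicate 2. The unmatched Mir486b is not in this median, and Mir144 and Mir451a come from 1 locus. The endothelial list had a median of 1.57 (percentile 99.6). All 3 tested members were higher in replicate 2 beyond counting error: Mir222 by 2.64, Mir221 by 1.57 and Mir126a by 0.37. None of them passed with the common dispersion over all genes (adjusted p = 0.107, 0.787 and 1 in the exact test of edgeR), and Mir221 and Mir222 are neighbours on chromosome X, so 2 of the 3 come from 1 locus. The miR-34 family lay barely outside, with a median of 1.355 against an upper bound of 1.353 (percentile 97.8). Mir34a at 1.36 and Mir34c at 3.26 were higher in replicate 2 and Mir34b at -0.46 was not called. The family came inside the central 95% in the column for either strand (percentile 95.9). The Dlk1-Dio3 locus, an imprinted region of chromosome 12 with 54 list members, had a median of -0.52, below all 10000 random lists. Beyond counting error, 18 of its members were higher in replicate 1 and 2 higher in replicate 2, while 21 were not called and 13 had too few reads. Mir127 (-0.61), Mir379 (-0.47) and Mir541 (-0.56) were among the 18, Mir411 (-0.14) was not, and no member passed with the common dispersion. These members come from 1 locus, and the random lists are of scattered genes.

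The other 14 lists lay inside the central 95%. Of the muscle list, Mir208a (0.82) and Mir208b (1.21) were higher in replicate 2 beyond counting error. Its 7 members that were not called included Mir499 (-0.02), and 1 member had too few reads. Of the epithelial list, 4 members were higher in replicate 2 beyond counting error, Mir203 at 0.43 among them. Another 2 were higher in replicate 1 and 1 was not called, for a median of 0.43 (percentile 90.4). The fibroblast list had a median of 0.90 (percentile 95.9), with Mir21a and Mir214 (0.98) higher in replicate 2 and Mir199b (-0.84) higher in replicate 1. Of the let-7 family, 6 members were higher in replicate 2, 3 higher in replicate 1 and 4 not called, for a median of 0.08. Of the miR-23/27/24 list, 2 were higher in replicate 2, 3 higher in replicate 1 (Mir23a at -0.69 and Mir23b at -0.57) and 1 not called, for a median of -0.24. Adjusted over the list alone, the counts of genes that differed beyond counting error were the same as over all genes in all 18 lists. With the common dispersion they were the same in 16 lists, and adjusted over the list alone Mir451a and Mir222 were called as well. Other scalings moved every log2 ratio by -0.03 (TMM) or -0.02 (DESeq2 size factors).

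**Figure D3:**
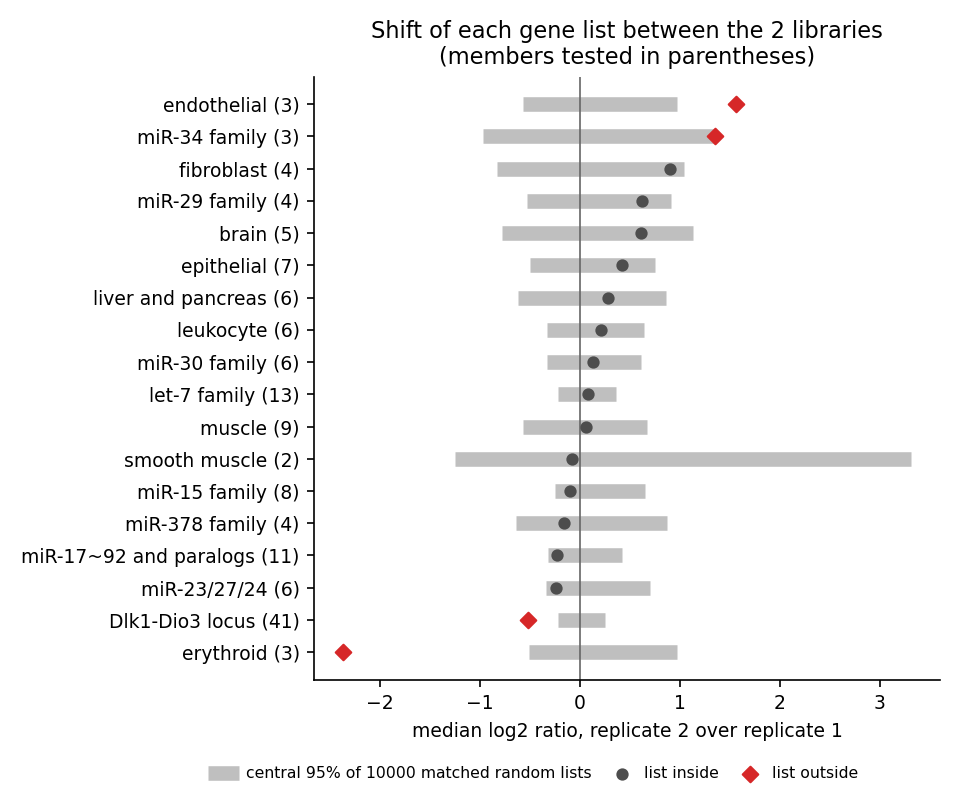
Median log2 ratio of replicate 2 over replicate 1 for the tested members of each of 18 gene lists (points), with the central 95% of 10000 random lists matched on size and expression (grey bars). The erythroid list (-2.37), the Dlk1-Dio3 locus (-0.52), the endothelial list (1.57) and the miR-34 family (1.36) lie outside their bars.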

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

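The comparison of copies across all genes and the test of red blood cell content were set before the data were examined. The comparison within clusters, the tests of the miRNAs higher in replicate 2 and the scaling test of the erythroid list were chosen only after the result was seen. The labels give 1 group, so no biological explanation from the design was tested for any pattern.

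Reads that no gene count holds were numerous: 3857758 reads in replicate 1 and 6355706 in replicate 2 mapped to several places, 1.27 and 1.20 times the reads in miRNA genes. On the opposite strand, where no other miRNA gene is annotated, reads above the 3 that a count of 0 allows were found in both libraries at 4 genes. Mir122 (chromosome 18, 65248861 to 65248926) had 46 and 101 such reads beside 91 and 67 sense reads. The values were 6 and 13 at Mirlet7b, 7 and 8 at Mir130a, and 5 and 10 at Mir5620.

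Low counts of miRNA genes with a near-identical copy, such as Mir24-1 and Mir29b-1, may come from reads left out because they map to several places. The planned comparison across genes (-0.22 in median log2(CPM + 1)) cannot decide this, because it rests on genes without reads and turns to +1.48 among genes with reads. Within 27 clusters of neighbouring hairpins, the members that share a 22-base stretch lay lower by a mean of -2.75 (SD 3.81; lower in 22 clusters; two-sided sign-flip permutation test, p = 0.00127), and the clusters of Mir1a-1 and Mir1a-2 are not among them because all their members share one. The clusters are not independent, because copies of 1 miRNA, such as Mir24-1 and Mir24-2 or Mir16-1 and Mir16-2, lie in different clusters. The p-value may therefore be too small. A difference within clusters argues against less active loci as the whole cause, since cluster members often share a transcript. How stable each mature miRNA is stays open, as do copies outside annotated hairpins and low genes without a 22-base copy, such as Mir133b.

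Mir205, Mir31, Mir200c and the neighbours Mir182, Mir183 and Mir96, genes picked by their ratios, were higher in replicate 2, although the epithelial list as a whole lay inside the central 95% of random lists (percentile 90.4). Depth or scaling would move all genes alike. Counts were already scaled to library totals, which largely set a median near 0 beforehand, so that median is no test of depth. The 6 were picked by their ratios, so their distance from the other genes was set beforehand too. The other 318 detected genes had a median log2 ratio of 0.0115 (SD 0.82), against at least 3.23 for each of the 6. Mir205, Mir182 and Mir96 had fewer than 10 reads in replicate 1, so they were not among the detected genes. The 6 were not alone above 3.23, because Mir135b (5.37), Mir26a-1 (3.27) and Mir34c (3.26) lay there as well. Cells of an epithelium that uses both Mir200 gene clusters would bring Mir200a, Mir200b and Mir429 too, but their median log2 ratio was -0.61 (SD 0.52). Mir141, the neighbour of Mir200c, was chosen after its values were seen and had 18 and 96 reads in replicates 1 and 2. Its log2 ratio was 1.62 (adjusted p = 0.859, exact test of edgeR), against 4.32 for Mir200c. RNA or reads carried over from another sample cannot be told apart from a true difference between the tissue pieces: Mir205 made up 0.196% of the counted reads of replicate 2, and single reads would be needed. An epithelium that does not use the second Mir200 cluster was not tested as a source.

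The erythroid list was lower in replicate 2, with a median log2 ratio of -2.37, and a difference in red blood cells left in the tissue may underlie it. Depth or scaling would move all genes alike. The other 318 detected genes had a median log2 ratio of 0.0175 (SD 0.91), so the list stood apart from them. Scaling to library totals largely set that median beforehand, so it is no test of depth. Red blood cell content cannot be told apart from other causes, because Mir486, the third tested member, went the other way (0.35) and is also made in muscle. Mir486b, the member not matched to a gene, is not in the list's median. Mir144 and Mir451a lie next to each other, and whether neighbours shift together was not decided here.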

How the results depend on the processing

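All alternatives below were set before the data were examined. Counts of detected genes followed the read minimum, with 554 genes at 1 read and 184 at 100 reads in both libraries against 321 at 10, and lay between 328 and 379 in each library alone. Of all reads in place of reads in miRNA genes, the 10 most abundant genes took 19.0% and the muscle list 0.374%, a change set by the larger denominator. In the column for either strand the muscle share was 1.73%, since that column has few or no reads at some abundant genes overlapped on the opposite strand, Mir378a among them. The number of genes that differed between the libraries fell from 224 to 12 with the common dispersion, which adds the spread between libraries to counting error, and stayed within 1.5 times the main count, at most 226, under TMM, DESeq2 size factors, a minimum of 1 read and the column for either strand. The biological coefficient of variation was 48.9% with genes down to 1 read and 37.6% with at least 100 reads in both libraries. The difference between hairpins with and without a copy turned to +1.48 (p = 0.00504, permutation test) among genes with at least 1 read and ranged from 0 to 0 without replicate 1 or without replicate 2 (p = 1), where both medians were 0. The erythroid shift ran from -3.06 to -2.37 and stayed outside the central 95% under all 4 alternatives, which are weak checks. TMM and DESeq2 scaling add 1 constant to every log2 ratio, so they could not change the percentile. Dropping the read minimum kept 3 tested members, and the column for either strand left 1. The Mir208 log2 ratio was 6.30 and 6.69 in each library alone. Leaving out a library leaves 1, so differences, dispersion and list shifts have no such check. Between groups, no paired analysis was possible because there is 1 group, while the Mir208 ratio is taken within each library. Depth limits rare genes, with floors of 0.988 CPM in replicate 1 and 0.568 CPM in replicate 2.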

Other observations

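The test of neighbouring genes was chosen only after the result was seen, and the lists were fixed before the data were examined.

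Immune miRNAs were present in both libraries. The leukocyte list took 0.962% ± 0.0969 of the reads (SD, n = 2), led by Mir155 (3380 CPM), Mir150 (2979 CPM), Mir146 (1692 CPM) and Mir342 (1027 CPM). Of its 7 members, 5 were higher in replicate 2 beyond counting error, 1 was higher in replicate 1 and 1 had too few reads. The median log2 ratio of 0.21 lay inside the central 95% of random lists. None of the members passed with the common dispersion.

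Families tied to cell growth were also expressed. The miR-15 family took 1.17% ± 0.0235 of the reads, led by Mir322 (3475 CPM), Mir15b (3225 CPM), Mir195a (2101 CPM) and Mir15a (1011 CPM). The miR-17~92 cluster and its paralogs took 1.23% ± 0.151, led by Mir93 (4616 CPM), Mir92-1 (3735 CPM), Mir17 (1231 CPM) and Mir106b (1110 CPM). The miR-34 family took 0.373% ± 0.234, nearly all from Mir34a (3675 ± 2276 CPM), and the Dlk1-Dio3 locus 0.193% ± 0.0465, led by Mir127 (722 CPM). Median log2 ratios were -0.10 for the miR-15 list, -0.23 for miR-17~92, 0.13 for miR-30, 0.63 for miR-29, -0.16 for miR-378, -0.08 for smooth muscle, 0.61 for brain, and 0.28 for liver and pancreas, all inside the central 95%.

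Unmapped reads made up 34.3% of replicate 2 and 19.4% of replicate 1.

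A hypothesis was that members of 1 genomic cluster shift together between the libraries. The median absolute difference in log2 ratio between members of a cluster was 0.52 over 148 pairs in 36 clusters, against 0.64 in shuffles (one-sided permutation test, p = 0.126). The test therefore decided neither way.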
